A study of Mus musculus with 2 samples.

How the data were processed

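Single-cell suspensions came from handpicked pancreatic islets of 15-week-old NOD/ShiLtJ mice on a diet of 20% HC or of 16% HC with 4% gluten. Per the labels, pancreata were perfused with collagenase P through the bile duct, islets were taken from a density gradient and dissociated with trypsin-EDTA, and cells of 3 mice were pooled for each of the 2 libraries. The authors deposited 1 table per library that holds raw counts, UMI counts per gene and cell barcode, with no normalization. Cell Ranger 4.0.0 and the mm10 build stand in the submitters' processing notes. How barcodes were called as cells, and the annotation release, are not given in the sources used here. Both tables list 31053 Ensembl gene identifiers, of which 30934 matched a symbol in GENCODE vM21, the annotation that was at hand and that need not be the authors'. The lowest barcode held 501 UMIs in both libraries.

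Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which left 7577 of 8200 and 7565 of 7758 barcodes. Doublets were scored with Scrublet in each library. Its own threshold marked 3 cells (0.0396%) with gluten and 179 (2.37%) with HC alone. The first count was taken as too low, which was not tested. The 6% of cells with the highest score were therefore removed in each library, 455 and 454 cells. This rule, like the removal of acinar genes from clustering, was set after seeing the data. The 7122 and 7111 kept cells held 78058738 and 105988366 UMIs.

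Counts were scaled to 10000 per cell and log-transformed. From the 2000 most variable genes over both libraries, 46 acinar genes were left out where present, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed, with no integration of the libraries. Acinar genes were the 15 fixed markers and genes at least 20-fold higher, at 200 CPM or more, in barcodes with at least 10% of their UMIs from those markers. Clusters were named "X-like" from markers of 26 cell types. The name of the type with the highest marker score was given unless fewer than 3 of its markers were raised, another type had more markers among the top 10 genes, another lineage reached 60% of the score, or the cells were shallow with no marker there. Markers of the kinds of T cell counted as T markers among the top 10. Cells outside acinar-like clusters with at least 5% of their UMIs from acinar markers were also kept out of the classes. T-like and NK-like cells, and myeloid cells, were clustered again at resolution 0.8 and named in the same way.

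Shares carry exact Clopper-Pearson 95% intervals, and differences of shares Newcombe intervals. For expression, UMIs were summed over the cells of a class in each library and divided by the class total (CPM). The log2 ratio has an exact interval from the conditional binomial of both counts. Against a count of 0 a floor of 3 counts was used, and the ratio is then set by that floor and is not an end of the interval. The 12 classes with at least 50 cells in each library were compared. A gene counted as measured with at least 50 UMIs in the library with the higher CPM, and as apart at 2-fold or more. With 1 library per diet there is no residual variation among samples, so no test across samples could be run, cells were not used as replicates, and intervals of shares and genes cover counting error only. Intervals of list medians are order-statistic intervals over the list's genes.

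The design held 35 gene lists. They cover beta cell identity, islet hormones, insulin processing and secretion, the unfolded protein response, oxidative stress defence, the interferon response, MHC class I and class II presentation, nuclear oxidative phosphorylation, the mitochondrial genome, and glycolysis and hypoxia. Others hold genes usually kept low in beta cells, immature or dedifferentiated beta cells, cell death and senescence, immediate early genes, proliferation and ribosomal proteins. For leukocytes there were cytotoxic effectors, T cell exhaustion, naive T cells, regulatory T cells, T helper cytokines, B cell activation, immunoglobulin constant regions, and inflammatory, homeostatic and complement or lysosome genes of macrophages. The rest were endothelial adhesion, fibroblast matrix, lymphoid aggregate chemokines, acinar enzymes and insulin as free RNA, regenerating islet-derived proteins, transglutaminases with gluten-related genes, and sex. A list's value is the median log2 ratio of members with at least 10 UMIs over both libraries, for lists with at least 3 such members. Beside it stands its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists, the markers, the filters on cells and the comparisons were fixed before the data were examined.

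Named genes follow a rule fixed at the same time. It ranks genes by the bound of their interval that lies nearer 0 and takes those where this bound is farthest out. It takes 12 in each direction for beta-like cells, 8 for other classes with at least 200 cells in each library and 3 for the rest. They need the same direction with TMM and at least 20% of the CPM of the class where the gene is highest. Left out are mitochondrial, ribosomal, haemoglobin, antigen receptor, Xist and Y-linked genes, genes without a proper name, and hormone or acinar genes outside their own class. The acinar genes here were the 46 above, a set extended after seeing the data. For each list, the 2 members with the most UMIs and the 2 whose nearer bound lay farthest from 0 were added. The text gives 222 gene and class pairs of these, and some other genes the rule takes are not reported here.

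The steps were tested on simulated data, Poisson counts drawn at the depth of beta-like, T-like and NK-like cells with 200 changed genes. Intervals covered the true ratio for 95.3% of genes in beta-like and 96.7% in NK-like sums. Simulated counts followed the law that the intervals assume and held no variation between cells. This coverage therefore does not extend to genes whose UMIs lie in few cells. Genes changed 2.5-fold were recovered at 100% in beta-like and 91.2% in NK-like sums. Of 200 lists of unchanged genes, 5.5% in beta-like and 3.5% in T-like sums lay outside the central 95% of random lists. Genes were drawn independently of each other, so these rates do not extend to lists whose genes vary together. Percentiles of such lists can be more extreme.

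Alternatives changed 1 choice at a time. For cells they were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), no filter, doublets kept, Leiden resolutions 0.5 and 2, subcluster resolutions 0.4 and 1.5, and classes from a marker score per cell. For expression they were TMM, median-of-ratios scaling, CPM without hormone, enzyme and mitochondrial genes, means of per-cell CPM, minimums of 20 and 200 UMIs, 1.5-fold, and list members with at least 50 UMIs. Chosen after seeing the data were Scrublet's own threshold, acinar genes kept in clustering, leaving out cells of 10 or more acinar UMIs, leaving out the top cell of each gene, and subcluster shares among named cells, as were medians within single clusters of beta-like, T-like and macrophage-like cells. Software was Python 3.11.15 with Scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.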

Results

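Pancreatic islet cells from 15-week-old NOD/ShiLtJ mice, an inbred strain that develops autoimmune diabetes, were profiled by single-cell RNA sequencing (10x Genomics, single cell 3' v3) after feeding on 1 of 2 diets. The diets held 20% of a component that the labels call HC and do not expand, or 16% HC with 4% gluten. Each diet had 1 library, made from cells pooled from 3 mice, so no replicate error exists, no test was made, and intervals of shares and of genes cover counting error only. Brackets hold 95% intervals throughout, and those of list medians run over the genes of the list. The library with gluten held 8200 barcodes and 88268070 UMIs (molecules counted by their unique molecular identifiers), and the library with HC alone held 7758 barcodes and 116900677 UMIs. After the filters 7122 and 7111 cells remained, with medians of 6392 and 5458 UMIs per cell. Values below give the library with gluten first, and log2 ratios are that library over the library with HC alone. The labels state no aim beyond the 2 diets, so the comparison asks how the make-up and the expression of islet cells differed between them.

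Among kept cells, the library with gluten held smaller shares of T-like and beta-like cells. Its shares of alpha-like, delta-like and endothelial-like cells were larger. With 1 preparation per diet, the recovery of cells from the tissue cannot be told apart from the diet. The same limit applies to the shares among endocrine, immune, T, NK and myeloid cells below. T-like cells made up 17.5% [16.6, 18.4] and 30.7% [29.6, 31.8], a difference of -13.2 percentage points [-14.6, -11.9]. Beta-like cells, the makers of insulin, made up 16.9% [16.0, 17.8] and 21.5% [20.6, 22.5], a difference of -4.61 points [-5.90, -3.32]. B-like cells made up 14.6% [13.8, 15.5] and 16.6% [15.7, 17.5], a difference of -1.95 points [-3.14, -0.757]. Alpha-like cells, which make glucagon, stood at 15.8% [15.0, 16.7] and 8.92% [8.26, 9.60], and somatostatin-making delta-like cells at 8.06% [7.44, 8.72] and 4.28% [3.82, 4.77]. PP-like cells, which make pancreatic polypeptide, made up 2.26% [1.93, 2.63] and 1.03% [0.805, 1.29]. That difference of 1.23 points [0.820, 1.66] was -0.017 points with coarser clusters (Leiden resolution 0.5), where that of delta-like cells was 4.70 points. Endothelial-like cells made up 4.39% [3.93, 4.90] and 2.07% [1.75, 2.43], and plasma-like cells, the antibody-secreting B lineage, 1.01% [0.792, 1.27] and 0.450% [0.308, 0.635]. Intervals of the difference held 0 for macrophage-like cells, at 3.61% and 3.05%, for NK-like cells, at 1.25% and 1.08%, and for plasmacytoid (pDC-like) and both types of conventional (cDC1-like and cDC2-like) dendritic cells. Immune classes together came to 43.1% [42.0, 44.3] and 56.3% [55.2, 57.5] of cells. The depth of a class differed between libraries beside these shares, with medians of 2233 and 2739.5 UMIs in T-like and 27299 and 37066 in beta-like cells. Wider gaps stood in macrophage-like cells, with 5765 and 12363 UMIs, and in endothelial-like cells, with 3569 and 6133. Clusters left unnamed for mixed markers held 3.99% [3.54, 4.47] and 1.88% [1.58, 2.23] of cells, and cells rich in acinar RNA that were kept out of the classes 0.182% and 0.0703%.

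**Figure D1:**
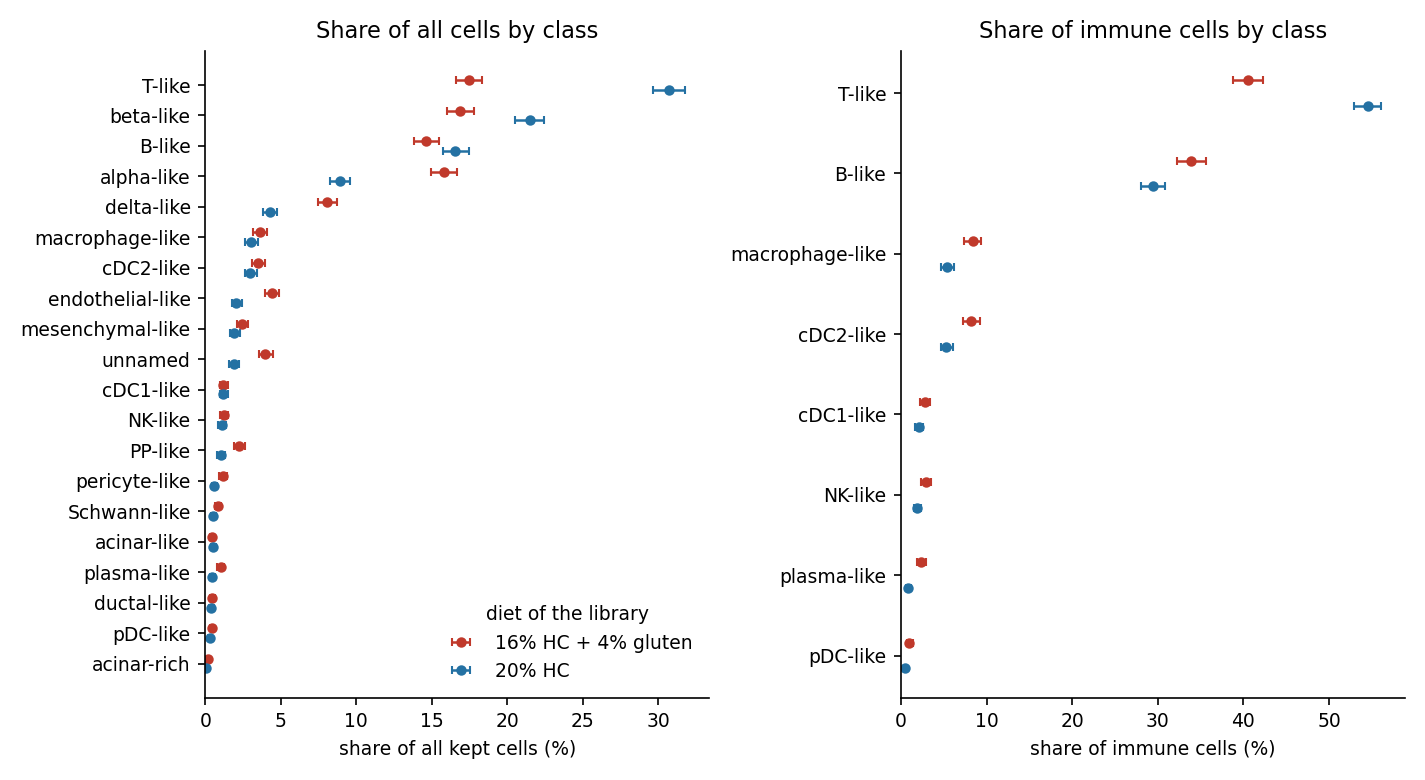
Share of each class among all kept cells (left) and of each immune class among immune cells (right), in percent. Points give 1 library per diet and bars the exact 95% binomial interval for counting error. T-like cells made up 17.5% of cells with gluten and 30.7% with HC alone, and alpha-like cells 15.8% and 8.92%.

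Among endocrine cells alone, beta-like cells made up 39.2% [37.5, 41.0] and 60.2% [58.3, 62.1], a difference of -20.9 points [-23.5, -18.4]. Alpha-like cells made up 36.8% of them with gluten, 11.8 points [9.40, 14.2] more than with HC alone, delta-like cells 18.7%, 6.76 points [4.88, 8.62] more, and PP-like cells 5.25% and 2.87%. Among immune cells alone, T-like cells made up 40.5% [38.8, 42.3] and 54.5% [52.9, 56.1], a difference of -14.0 points [-16.3, -11.7]. With fewer T-like cells, other immune classes took larger shares of the kept immune cells with gluten. B-like cells stood at 33.9% and 29.4% of immune cells, macrophage-like cells at 8.37% and 5.42%, and cDC2-like cells at 8.17% and 5.32%. The myeloid classes include shallow subclusters, described below, that differ in size between the libraries. Plasma-like cells stood at 2.34% and 0.799%, a difference of 1.55 points that became 6.46 points at Leiden resolution 0.5 and 0.649 points with acinar genes kept in the clustering. NK-like cells made up 2.90% and 1.92%, a difference of 0.976 points that was 0.204 [-0.653, 1.10] with classes from a marker score per cell, and pDC-like cells 0.977% and 0.499%. Differences for cDC1-like cells, 2.80% and 2.12%, were within counting error (0.679 points [-0.043, 1.44]).

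Among the 1333 and 2261 T-like and NK-like cells, clustered again, NK, gamma delta T and type 2 innate lymphoid (ILC2) subclusters took larger shares with gluten. NK subclusters held 6.23% [4.99, 7.66] and 2.87% [2.23, 3.65] of these cells, gamma delta T subclusters 2.70% [1.90, 3.72] and 0.840% [0.507, 1.31], and ILC2 subclusters 1.80% and 0.663%. Among cells of named subclusters alone, these differences were 3.92 points [1.30, 6.65], 2.64 points [0.990, 4.48] and 1.52 points [0.124, 3.09]. The gamma delta T subcluster had 5 of its markers raised. Its top 10 genes held only 1 of them, Cd163l1, beside Cd74 and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1. CD8 T subclusters held 15.5% and 12.2%, a difference of 3.29 points [0.971, 5.70] that was -1.91 points [-6.05, 2.29] among named cells. Proliferating cells held 7.65% and 5.22%, but their difference among named cells, 0.916 points [-2.17, 4.08], held 0. CD4 T subclusters held 15.6% and 14.2%, a difference of 1.45 points [-0.929, 3.92] that was 4.77 points [2.27, 7.36] with doublets kept, 4.16 under the stricter filter and -6.26 [-10.5, -1.96] among named cells. Regulatory T subclusters held 9.45% and 7.30%, a difference of 2.15 points that was -2.28 points at subcluster resolution 1.5 and -0.838 points among named cells. Unnamed subclusters, here those without 3 raised markers of a kind, held 41.1% and 56.8%. The difference for unnamed cells changed sign, to 6.67 points, at resolution 0.4. Those cells were another group, as they included a subcluster of 344 and 445 cells with 6 regulatory T and 5 CD4 T markers raised. Among 624 and 535 myeloid cells, monocyte subclusters held 7.37% and 11.2%, a difference of -3.84 points [-7.30, -0.503] that was -3.14 [-7.45, 1.16] among cells of named subclusters. Mature dendritic subclusters held 4.97% and 8.97%, a difference of -4.00 points [-7.09, -1.08], or -3.82 [-7.64, -0.0468] among named cells. Of these, 51 cells lay in a subcluster with Ccr7 and Fscn1 raised and 28 in another with Fscn1 but not Ccr7. Unnamed myeloid subclusters took 29.2% and 17.2%, so named subclusters together took a smaller part of the cells with gluten. Among the unnamed, a subcluster scoring highest for macrophage markers held 69 and 21 cells, with medians of only 912 and 971 UMIs. Another held 51 and 19 cells, with medians of 935 and 1136 UMIs. Both had Ins1 and Ins2 among their top genes.

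RNA of digestive enzymes from acinar cells was spread over cells of other classes in the library with gluten. Of B-like cells, 7.77% [6.22, 9.57] held 10 or more UMIs of 15 acinar genes there, against 0 of 1179 with HC alone (0% [0, 0.312]). Of T-like cells, 6.83% and 0.137% did so, of alpha-like cells 9.85% and 0.158%, and of beta-like cells 8.15% and 0.196%. With every cell thinned to 1 depth per class, the shares were 6.39% and 0% in B-like cells at 1666 UMIs (260 and 122 shallower cells left out) and 7.10% and 0.154% in beta-like cells at 21941 UMIs (301 and 229 left out). Carriers were present in both libraries among delta-like cells, with 16.2% and 17.8%, PP-like cells, with 16.1% and 11.0%, and ductal-like cells, with 12.9% and 11.1%. In delta-like cells the summed acinar UMIs stood at 575 and 453 CPM. The acinar list's median log2 ratio was yet 2.77 there, with 1 of 14 genes lower. In PP-like cells the sums were 225 and 148 CPM. A few genes may thus hold much of the acinar UMIs in both classes, which was not examined. The acinar list had medians from 1.73 in PP-like to 3.58 in endothelial-like cells, each at the 100th percentile of random lists. Without the cells of 10 or more acinar UMIs, these medians came to between 0.06 and 1.25 in the 11 classes that kept a value. Acinar-like cells themselves made up 0.421% and 0.506% of cells. That difference, -0.085 points [-0.316, 0.143], was 1.81 with acinar genes kept in the clustering, 1.18 under the stricter filter, 3.05 with classes from a marker score per cell and -0.635 [-1.06, -0.213] at Leiden resolution 0.5.

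**Figure D2:**
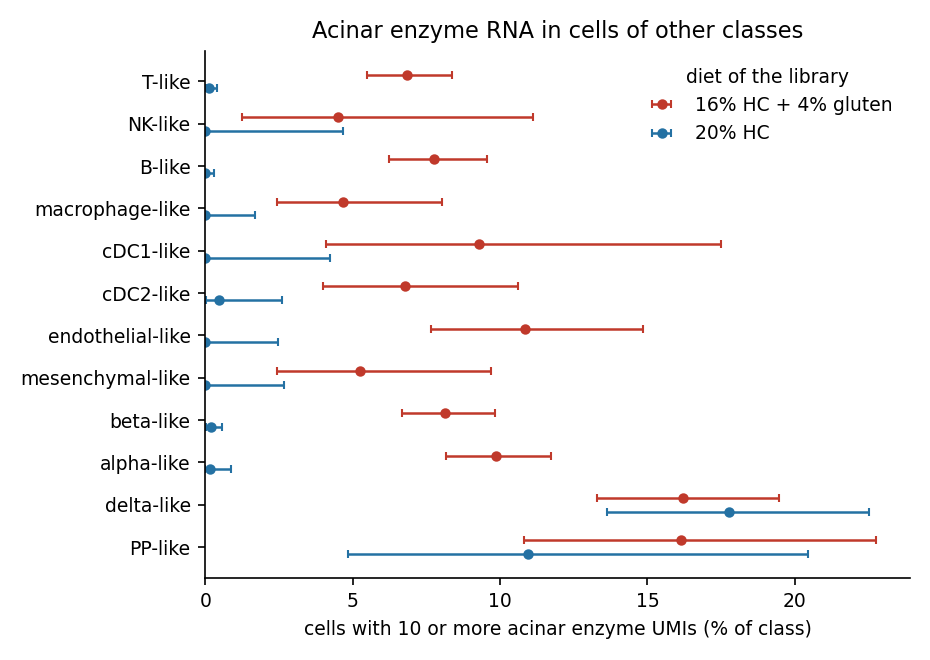
Percent of cells in each class with 10 or more UMIs of 15 acinar enzyme genes, 1 point per library with its exact 95% binomial interval. B-like cells stood at 7.77% with gluten and 0% with HC alone, and delta-like cells at 16.2% and 17.8%.

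Sums of UMIs over the cells of a class were compared in 12 classes, as counts per 1000000 UMIs (CPM). In beta-like cells 155 of 10912 measured genes were at least 2-fold higher with gluten and 49 at least 2-fold lower. The counts were 193 and 53 of 9529 in alpha-like, 81 and 75 of 7933 in delta-like, and 128 and 9 of 5597 in PP-like cells. T-like cells had 151 and 183 of 8121, NK-like cells 37 and 18 of 811, and B-like cells 88 and 196 of 5923. Macrophage-like cells had 136 and 116 of 4850, cDC1-like cells 55 and 54 of 2794, and cDC2-like cells 133 and 149 of 4825. Endothelial-like cells had 105 and 18 of 4445, and mesenchymal-like cells 146 and 267 of 5004. The part that was higher moved by over 10 points with another scaling in 3 classes. It was 31.0% of the genes 2-fold apart in B-like cells and 45.8% with TMM scaling, 47.2% and 68.8% in cDC2-like cells, and 78.5% in alpha-like cells and 65.1% without hormone, enzyme and mitochondrial genes. TMM shifted all log2 ratios by 0.10 in B-like and NK-like and by 0.18 in cDC2-like cells, and median-of-ratios scaling by 0.10 in B-like and 0.15 in cDC2-like cells. CPM without those genes shifted them by -0.11 in PP-like and -0.10 in alpha-like cells.

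Beta-like cells of the library with gluten carried more RNA of immediate early genes. Members of the beta cell identity list lay on both sides of 0. All 20 members of the list of immediate early genes, which tissue dissociation is known to induce, were higher, each with an interval above 0 (median 1.68 [1.44, 2.34]). Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039 in mm10), a stress-induced transcription factor, had a log2 ratio of 4.04 [3.90, 4.17], at 128 and 7.81 CPM. The heat shock co-chaperone Dnajb1 (ENSMUSG00000005483, chromosome 8, 83608193 to 83612653) stood at 3.28 [3.22, 3.34], with 407 and 42.0 CPM. Also higher were the transcription factors Maff, at 3.27, and Npas4, at 2.26, and the AP-1 subunits Fosb (2.10), Jun (1.61) and Fos (1.44). Zfp36, which promotes decay of cytokine mRNA, stood at 2.45. The inhibitors of cytokine signalling Socs3 and Cish stood at 2.34 and 2.43. Irs2, an adaptor of the insulin receptor, had 2.02 [1.89, 2.16], and the inositol kinase gene Itpkc had 2.15. The metal-binding metallothioneins Mt1 and Mt2 had 1.81 [1.79, 1.83], at 1381 and 394 CPM, and 1.92 [1.87, 1.97], while Mt3 had -1.04.

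Genes lower in beta-like cells with gluten included most of the MHC class I and interferon response lists. Sdf2l1, a partner of the chaperones of the endoplasmic reticulum, had -0.81 [-0.85, -0.77], and the protein disulfide isomerase gene Pdia5 had -1.07 [-1.28, -0.87]. The chaperone Hspa5 was higher, at 0.75 [0.73, 0.76], and Hsp90b1 stood at -0.14, so members of the unfolded protein response list lay on both sides of 0 (7 of 19 higher, median -0.14 [-0.48, 0.59], 3.86th percentile). The homeobox gene Nkx6-2 had -3.68 [-5.15, -2.52] at only 0.167 and 2.14 CPM. Amd2, of polyamine synthesis, had -1.59, the metal transporter gene Slc39a8 -0.98, and the lens crystallin gene Cryba2 -0.71. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the light chain of MHC class I, had -0.89 [-0.92, -0.86], at 414 and 767 CPM. Of the MHC class I list, 13 of 15 members were lower (median -0.46 [-0.74, -0.31], 0th percentile), H2-D1 among them at -0.50, while H2-Q7 had 0.98. Of the interferon response list, 20 of 25 were lower (median -0.45 [-0.62, -0.32], 0th percentile). The interferon-induced GTPase Iigp1 had -1.61 [-1.68, -1.54], whereas the transcription factor Irf1 had 1.59 and the chemokine Cxcl10 0.30 [0.24, 0.35]. Beta-like cells lay in 3 clusters, which held 76.8%, 13.8% and 9.39% of them with gluten and 52.1%, 30.5% and 17.5% with HC alone, the last with Iigp1 and Cxcl10 among its top genes. Within these clusters the interferon medians were -0.47, 0.03 and 0.51 and the MHC class I medians -0.67, 0.04 and 0.40. Both lists were thus lower in 1 of the 3, and the shares of the clusters enter the values for the class. The clusters were formed from the same expression values, which can sort cells by interferon genes. Medians near or above 0 therefore do not show that these genes had not fallen in the cells of those clusters. Immediate early medians were 1.61, 1.70 and 1.87 in the 3 clusters. The MHC class II list had a median of -0.53, with Cd74 at -0.26 and H2-Ab1 at -0.64, at levels far below those of B-like cells.

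The beta cell identity list had a median of -0.04 [-0.15, 0.09] over 15 genes, at the 59.3th percentile, with the interval above 0 for 4 members and below 0 for 7. The glucose-6-phosphatase gene G6pc2 had -0.33 [-0.36, -0.30] and the incretin receptor Glp1r 0.84 [0.32, 1.37]. Ins2 had 0.03 and Ins1 -0.11, inside a hormone list with a median of 0.03. The list of insulin processing and secretion had a median of -0.07, with the prohormone convertases Pcsk1 and Pcsk2 at -0.28 and -0.32. Nuclear genes of oxidative phosphorylation had a median of -0.10, with 15 of 18 lower, among them Ndufa4 at -0.47. Oxidative stress defence had a median of 0.02, with the peroxiredoxin Prdx1 at -0.19, and glycolysis and hypoxia a median of 0.04, with Vegfa at 0.30. The list of immature or dedifferentiated beta cells had a median of 0.25 over 8 genes (95.6th percentile), with Npy at 0.78 [0.71, 0.84]. Cell death and senescence genes had a median of 0.12, with the p53 target Bbc3 at 0.91 and Bax at -0.12. Genes usually kept low in beta cells had a median of 0.08 over 8 genes, or -0.65 over members with at least 50 UMIs. Proliferation genes had a median of 0.25 over 16 genes [-0.49, 0.73].

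**Figure D3:**
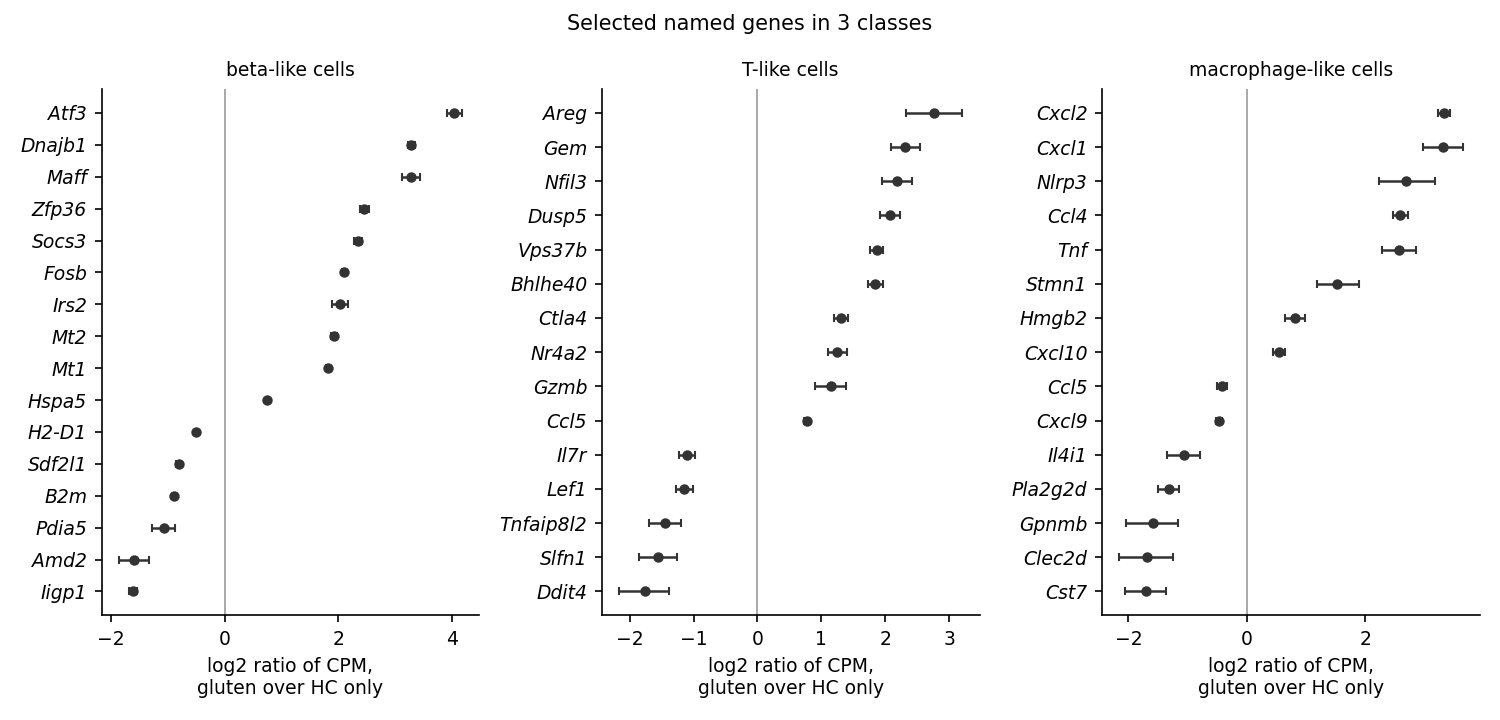
Log2 ratio of CPM, gluten over HC alone, for selected genes in beta-like, T-like and macrophage-like cells. Points are 1 library against the other, and bars the exact 95% interval for counting error. In beta-like cells the values run from 4.04 for Atf3 to -1.61 for Iigp1.

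Alpha-like cells repeated both parts of this pattern. The immediate early list had a median of 0.83 [0.36, 1.52] with 18 of 20 members higher. Csrnp1, a nuclear protein gene induced by signalling, had 3.01 [2.74, 3.29], Maff 2.86, Atf3 2.08, the apoptosis inhibitor Birc3 2.87 [2.48, 3.29] and the NF-kappa-B regulator Nfkbiz 2.14. Mt2 stood at 2.33 and Mt1 at 1.93. The interferon list had a median of -0.79 [-1.02, -0.43] with 21 of 25 lower, and the MHC class I list a median of -0.73 [-0.92, -0.22] with 13 of 15 lower. B2m had -1.25 [-1.27, -1.22], at 1625 and 3860.4 CPM, the immunoproteasome subunit Psmb9 -1.17, H2-D1 -0.80 and Iigp1 -1.79, against 1.26 for Irf1 and 0.74 for Cxcl10. Rgs2, a regulator of G protein signalling, had -1.18, and the thioredoxin inhibitor Txnip -0.93. Gcg had -0.13. All 9 hormone genes were lower in these cells (median -0.53), most of them hormones of other islet cells, and that median was -0.09 with doublets kept. The unfolded protein response list had a median of 0.11, with Hspa5 at 0.65.

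Delta-like cells had the lowest interferon median of the 10 classes and the lowest MHC class I median of the 8 classes for which these lists were fixed. The interferon list had a median of -1.17 [-1.45, -0.94] with 23 of 25 lower, and the MHC class I list a median of -1.05 [-1.14, -0.62] with 15 of 15 lower. The guanylate-binding protein gene Gbp7 had -2.05 [-2.35, -1.76], Rtp4 -1.40 and Iigp1 -1.93. B2m had -1.29 [-1.35, -1.24], at 793 and 1944 CPM, with H2-D1 at -1.07, H2-K1 at -1.05 and the immunoproteasome subunit Psmb8 at -1.14. Immediate early genes were higher in 20 of 20 (median 1.09 [0.86, 1.43]), with Atf3 at 3.77 [3.50, 4.06]. Further higher genes were C2cd4b at 2.53 [2.35, 2.70], the cell cycle kinase Wee1 at 3.35, and the transcription factors Maff at 2.57 and Egr3 at 2.73. Tiparp, a target of the aryl hydrocarbon receptor, had 1.87. The opioid peptide precursor Pdyn had -1.21 and Sst 0.12. The hormone list had a median of -0.19 in these cells, with Ppy at -1.24, or -0.37 without the top cell of each library. PP-like cells, 161 and 73 in number, had a median of 0.94 for the immediate early list, Maff at 3.27 [2.63, 3.98] (2.52 at Leiden resolution 0.5), Csrnp1 at 3.19 and Atf3 at 2.13. Their Bambi had -1.11. Ppy had -0.90 [-0.91, -0.89] and Limch1 -1.61, but 0.37 and 0.13 at Leiden resolution 0.5.

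**Figure D4:**
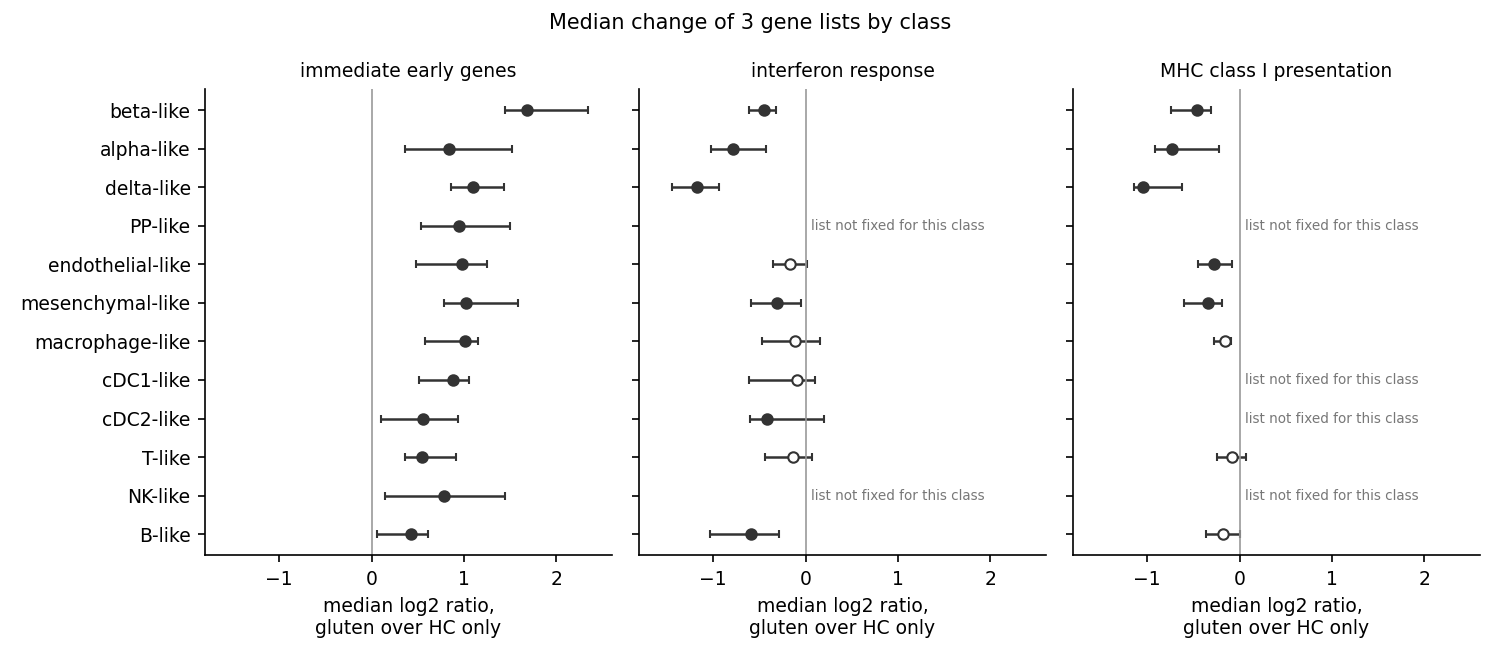
Median log2 ratio of 3 gene lists in each class, gluten over HC alone, with the 95% order-statistic interval over the list's genes. Filled points lie in the outermost 2.5% at either end of 10000 random lists matched on expression. Immediate early genes lie above 0 in each class, up to 1.68 in beta-like cells, and the interferon list lies at -1.17 in delta-like cells.

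T-like cells of the library with gluten had higher Areg and several transcription factors and regulators of signalling, and lower Il7r and Lef1 of naive T cells. Several subclusters without a name were split by library. The subcluster with Ccr7 and Klf2 raised held 411 and 26 cells, that with Lef1 raised 31 and 634, and that with S1pr1 and Il7r raised 46 and 341. Areg (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432), a ligand of the epidermal growth factor receptor, had 2.76 [2.33, 3.21], at 46.7 and 6.90 CPM. Gem, a small GTPase gene, had 2.31 [2.08, 2.54], the transcription factors Nfil3 and Bhlhe40 2.19 and 1.85, the MAP kinase phosphatase Dusp5 2.07, Vps37b 1.87 and Irs2 2.16. Lower were Ddit4, an inhibitor of mTOR signalling, at -1.77 [-2.17, -1.39], Slfn1, linked to T cell quiescence, at -1.55 [-1.85, -1.26], the immune checkpoint gene Tnfaip8l2 at -1.45, and Nab2, a repressor of early growth response factors, at -1.62. The naive and stem-like list had a median of -0.29 [-1.10, 0.35] with 3 of 11 higher (0.07th percentile), with the interleukin 7 receptor Il7r at -1.10 [-1.23, -0.97] and the transcription factor Lef1 at -1.14 [-1.28, -1.01], and Klf2 at -0.09. Il22, the interleukin 22 gene, had 0 UMIs with HC alone and a log2 ratio of 5.88 against a floor of 3 counts. That ratio was 4.28 without the top cell, so 1 cell held much of its RNA. Il17a had 4.87 [2.87, 7.98], at 6.82 and 0.234 CPM. The immediate early list had a median of 0.54 [0.36, 0.92], with Junb at 1.07.

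Lists of T cell function moved in different directions, as did the 5 clusters of T-like cells. The cluster with Ccl5 and Nkg7 among its top genes held 20.9% and 14.7% of the class, that with Ctla4 and Tnfrsf4 28.7% and 22.6%, and that with Lef1 and Il7r 30.1% and 42.4%. Within the 5 clusters, medians ran from -0.48 to 0.52 for cytotoxic, -0.50 to 0.98 for checkpoint, 0.03 to 0.52 for regulatory T and -0.89 to 0.14 for naive genes, so the make-up of the class enters the values below. The cytotoxic median was -0.12 in the cluster with Ccl5. Over the class, cytotoxic effectors were higher in 12 of 14 (median 0.28 [0.05, 0.77], 99.96th percentile), with the chemokine Ccl5 at 0.77 [0.74, 0.80], at 3468 and 2036 CPM, and granzyme B (Gzmb) at 1.15 [0.91, 1.39], or 0.53 under the stricter cell filter. Nkg7 had 0.15, and -0.02 with acinar genes kept in the clustering. Checkpoint and exhaustion genes had a median of 0.21 [-0.16, 1.31] over 11 genes (99.5th percentile), with Ctla4 at 1.31 [1.21, 1.42] and Nr4a2 at 1.25 [1.11, 1.40], and the regulatory T list a median of 0.31 (99.8th percentile), with Tnfrsf4 at 0.18. Ctla4 stands in both lists. Helper cytokines and regulators had a median of -0.03, with interferon gamma (Ifng) at -0.04 [-0.19, 0.10] and Cd40lg at -0.93. Over all cells of a library, Ifng had a log2 ratio of -0.46 [-0.58, -0.34]. The interferon list had a median of -0.13 [-0.44, 0.07] in T-like cells, with Irf1 at 0.95 and Cxcl10 at 1.98, and MHC class I a median of -0.08. Proliferation genes had a median of -0.22, with Cdk1 at -0.56 and Hmgb2 at 0.01, but 0.32 at Leiden resolution 0.5 and 0.09 by means of per-cell CPM. Nuclear oxidative phosphorylation had a median of 0.03. In NK-like cells, 89 and 77 in number, Vps37b had 2.71 [2.27, 3.18], the kinase Pim3 2.27 [1.47, 3.16] and Gem 1.98. Gzmb and Il7r were lower there, at -1.93 [-2.57, -1.35] and -1.69. Their cytotoxic list had a median of 0.12, with Ccl4 at 1.67, Ccl5 at 0.10 and Gzma at -0.51, the last at 0.16 without the top cell of each library.

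B-like cells fell mostly into different clusters in the 2 libraries, cluster 1 with 853 of the 1042 cells with gluten (81.9%) and cluster 2 with 943 of the 1179 with HC alone (80.0%). Their higher genes included Rnf125, a ubiquitin ligase gene, at 3.22 [2.30, 4.29], the transcription factors Nfil3 and Ets2 at 2.45 [1.76, 3.20] and 2.23 [1.74, 2.75], Irs2 at 1.89 and Vps37b at 1.43. Lower were Clec2i at -2.11 [-2.80, -1.48], the adaptor gene Hsh2d at -2.24 [-3.13, -1.45], and Zfp36l2 at -1.51 [-1.70, -1.32]. The small GTPase genes Gimap7 and Gimap1 had -1.56 and -1.38, and Insig2, of sterol control, -1.81. The interferon list had a median of -0.60 [-1.03, -0.29] with 17 of 22 lower (0th percentile), against 0.67 for Irf1, 1.78 for Cxcl10 and 1.31 for the checkpoint ligand Cd274. MHC class I genes had a median of -0.18, with Psmb8 at -0.67. MHC class II genes had a median of 0.00, with Cd74 at 0.14 and their transactivator Ciita at -0.76 [-0.98, -0.53]. Activation and germinal centre genes had a median of -0.10, with Cd69 and Cd83 at -0.18 and -0.18. Immunoglobulin constant regions had a median of -0.08, with Ighd at -0.73, Iglc3 at -1.06, Ighm at 0.10 and Igkc at 0.05. With acinar genes kept in the clustering, Ighm stood at -0.70 and Igkc at -0.37. Proliferation genes had a median of 0.17, with Hmgb2 at 0.80, and immediate early genes a median of 0.42 [0.06, 0.61].

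Macrophage-like cells with gluten carried more RNA of inflammatory chemokines and cytokines, and of immediate early genes. The immediate early list was higher in 20 of 20 (median 1.02 [0.58, 1.16], 100th percentile). Here too, another handling of the tissue cannot be told apart from the diet. The neutrophil-attracting chemokine Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) had 3.33 [3.23, 3.43], at 3737 and 372 CPM, and Cxcl1 had 3.31 [2.98, 3.64]. Ccl4 had 2.59, tumour necrosis factor (Tnf) 2.57 [2.29, 2.86] and the inflammasome sensor Nlrp3 2.69 [2.23, 3.17]. The inflammatory macrophage list was higher in 12 of 16 (median 0.98 [-0.28, 2.31], 100th percentile), while its members Cxcl9 and Ccl5 had -0.47 [-0.51, -0.42] and -0.43. In 3 myeloid subclusters with at least 20 such cells in each library, its medians were 0.82, 0.63 and 1.87. The first and second were named macrophage, and the third, with 36 and 51 cells of the class, monocyte. Immediate early medians in the same subclusters were 0.97, 0.87 and 0.87. At subcluster resolution 1.5, a macrophage subcluster with Mmp12, Ccl4, Cxcl2 and Tnf among its top genes held 63 and 5 cells. Another, led by Mrc1, held 22 and 10, and the remaining 2 held 42 and 78 and 23 and 50. The elastase Mmp12 had 6.64 [4.76, 9.70], Mir155hg 4.12 [2.80, 5.80] and the lysozyme gene Lyz1 2.92, or 2.31 without the top cell of each library. Lyve1 had 0 UMIs with HC alone and a log2 ratio of 3.98 against the floor of 3 counts, or 2.44 at Scrublet's own threshold. Lower were the cystatin gene Cst7 at -1.71 [-2.06, -1.37], Clec2d at -1.69, Gpnmb at -1.59 [-2.04, -1.16], the phospholipase Pla2g2d at -1.32, complement factor B (Cfb) at -1.27 and Il4i1 at -1.07.

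The homeostatic or repair list had a median of 0.05 in macrophage-like cells, with Apoe at 0.09, and the complement and lysosome list a median of -0.10, with C1qa at -0.07 and Ctsd at -0.41. Proliferation genes were higher in 13 of 17 (median 0.67), with Stmn1 at 1.53, Rrm2 at 1.95 and Hmgb2 at 0.82, but that median was 0.22 with doublets kept and 0.09 at Scrublet's own threshold, where Rrm2 had 0.35. Their interferon list had a median of -0.12 [-0.47, 0.16], with Isg15 at 0.77 and Cxcl10 at 0.54. MHC class I genes had a median of -0.16, or -0.32 at Scrublet's own threshold, and MHC class II genes a median of 0.04, with Cd74 at 0.23. Glycolysis and hypoxia had a median of 0.09 and nuclear oxidative phosphorylation a median of -0.02.

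In cDC2-like cells the decoy receptor Il1r2 had 3.25 [2.84, 3.67], the urokinase receptor Plaur 2.47 [1.99, 2.98], the nuclear receptor Nr4a3 2.30, the NF-kappa-B subunit Rel 1.93 [1.73, 2.13], Nfil3 2.29 and Mir155hg 3.29. The chemokine Ccl17 had 3.80 [2.51, 5.47], or 3.08 at Scrublet's own threshold. At subcluster resolution 1.5, a subcluster scoring highest for cDC2 markers but left unnamed, with Il1r2 among its top genes, held 88 and 18 cells, and another such subcluster 10 and 55. Lower in the class were galanin (Gal) at -3.11 [-4.62, -1.90], Tmprss11d at -2.83, the calcium channel gene Ryr3 at -2.32 and Tifab at -2.16. Their interferon list had a median of -0.41 [-0.60, 0.20] at the 0.01th percentile, with Usp18 at -1.46 (-0.58 by means of per-cell CPM), against 0.97 for Cxcl10. MHC class II genes had a median of -0.01 there, with Ciita at -0.98 [-1.17, -0.79]. That median was 0.17 with TMM scaling and -0.31 [-0.52, -0.18] at Scrublet's own threshold. The cDC1-like cells, 86 and 85 in number, scored 3.31 for cDC1 and 2.86 for mature dendritic markers, with 7 of the latter raised. The class may thus hold both kinds, and its make-up may enter its values. It had Cxcl10 at 3.17 [2.74, 3.62], at 393 and 43.7 CPM, Nfil3 at 3.69 [2.70, 4.87] and ornithine decarboxylase (Odc1) at 2.03. Pfkfb3, of glycolysis, had -1.95, Anxa3 -1.60 and Nabp1 -1.54. Iigp1 had -1.50, or -0.75 by means of per-cell CPM, within an interferon list with a median of -0.09, and Ciita -0.98 within an MHC class II list with a median of 0.07. Immediate early medians were 0.89 [0.51, 1.05] in cDC1-like and 0.56 [0.10, 0.94] in cDC2-like cells.

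Endothelial-like cells had higher immediate early genes (median 0.98 [0.48, 1.25]), with Egr1 at 1.47 [1.34, 1.60] and Junb at 1.27. The growth arrest gene Gadd45b had 2.23 [1.91, 2.56] and the matrix protein gene Ccn1 2.07 [1.86, 2.29]. Most antigen presentation genes were lower. MHC class II had a median of -0.64 [-0.83, 0.61] with 9 of 11 lower, with Cd74 at -0.64 [-0.69, -0.58], H2-Ab1 at -0.89, and MHC class I a median of -0.28 [-0.45, -0.08] with 15 of 15 lower, 9 of them with an interval below 0, with H2-T23 at -0.78. The interferon list had a median of -0.17 [-0.35, 0.01], or -0.43 with doublets kept, with Gbp7 at -0.91 and Gbp4 at -0.88. Cxcl10 had 0.59, or -0.14 by means of per-cell CPM. The protease inhibitor Serpina1b had 450.4 and 899.8 CPM. The adhesion and activation list was lower in 11 of 15 (median -0.32, 0.085th percentile), yet its vessel addressins rested on few cells. Madcam1, the mucosal addressin, had -1.56, or -0.59 without the top cell of each library. Glycam1 had -0.74, or -0.09 without the top cell and 0.57 with doublets kept. Ccl21a had -6.08, or -0.51 without the top cell.

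Mesenchymal-like cells, 172 and 137 in number, had higher immediate early genes (median 1.02 [0.78, 1.59]), with Fosb at 2.21 [2.01, 2.41] and Egr1 at 1.99. The matrix and lymphoid stroma list was higher in 11 of 16 (median 0.20, 97.2th percentile), with Sparc at 0.35, Col3a1 at 0.31 and the B cell chemokine Cxcl13 at 2.37 [2.23, 2.52]. MHC class I genes were lower in 15 of 15 (median -0.34 [-0.60, -0.19]), with Psmb8 at -0.71, and interferon genes in 20 of 24 (median -0.31 [-0.59, -0.05]), with Cd274 at -2.39, or -0.89 with doublets kept. Genes at low counts stood at the extremes of this class: Trem2 at 7.12, Lgals7 at 5.65, Tmem108 at 5.16, Ms4a4c at -4.28, Bcl2a1a at -3.84 and Ccl21a at -6.21. With doublets kept, the last 3 stood at -2.10, -1.40 and -1.40.

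Across the 12 classes, mitochondrial genome transcripts had medians from 0.11 in NK-like to 0.33 in cDC2-like cells. In beta-like cells that median was 0.29 (12 of 13 higher), with mt-Atp6 at 0.49, and in cDC1-like cells 0.21, or -0.13 by means of per-cell CPM. Ribosomal protein genes had medians of 0.27 in PP-like, 0.21 in alpha-like and 0.09 in delta-like cells, and between -0.09 and 0.04 in the other classes. The list of transglutaminases and gluten-related genes, with 3 to 8 measured members, ranged from -0.95 in B-like to 0.49 in beta-like cells (98.4th percentile). Its members included Tlr2 at 0.51 [0.26, 0.76] in beta-like and 1.24 [0.78, 1.72] in cDC2-like cells, and the transglutaminase Tgm2 at 0.79 [0.54, 1.04] in mesenchymal-like cells. Chemokines of lymphoid aggregates, summed over all cells of a library, had a median of -0.05 over 12 genes (6.71th percentile). Insulin RNA outside beta-like cells had medians of 0.90 in B-like, -0.24 in T-like, 1.95 in endothelial-like and -1.20 in macrophage-like cells, and became 0.04, 0.12, 0.20 and 0.19 with doublets kept. The median percent of Ins1 and Ins2 UMIs per cell went against the negative sums. It was 1.69% and 0.934% in T-like and 0.778% and 0.419% in macrophage-like cells. The list of regenerating islet-derived proteins had fewer than 3 measured members in each class compared. Xist, transcribed from the inactive X chromosome, had 53615 and 53572 UMIs over all cells. Of the genes of the Y chromosome in the same list, Ddx3y and Eif2s3y had 0 UMIs in both libraries, Uty 4 and 2, and Kdm5d 1 and 2.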

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

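The tests of acinar RNA and the quality and handling tests of immediate early genes were chosen after their results were seen, and the other tests before. Barcodes over the limit of 20% mitochondrial UMIs entered no comparison. They came to 7.21% [6.66, 7.79] of barcodes with gluten and 2.36% [2.03, 2.72] with HC alone, and held medians of 1281 and 1558 UMIs. Clustered without a filter, 484 of 591 and 133 of 183 of them stayed unnamed. Clusters left unnamed among kept cells, likewise outside the comparisons, held 3.99% and 1.88% of cells. One of them, with markers of both T and B cells, held 141 cells (1.98%) with gluten and 10 (0.141%) with HC alone, and the other, between beta and delta cells, 143 (2.01%) and 124 (1.74%).

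Immediate early genes were higher in each compared class of the library with gluten. Shallow cells or cells high in mitochondrial RNA are argued against as the whole cause. In beta-like cells with at least 37066 UMIs and at most 2.01% mitochondrial UMIs, the medians with HC alone, 118 and 481 cells were left, and the list stood at 1.70 with members from 0.41 to 4.14. Free RNA of stressed cells would add about the same UMIs to every class, but the median gains were not alike. They were 4.51 UMIs per beta-like and 0.0043 per B-like cell, or 5.51 and 0.035 with the libraries at equal depth. The ratios, 1039 and 156, rest on gains near 0 in B-like cells and give no effect size. Another handling of the tissue in 1 preparation cannot be told apart from the diet, because each diet had 1 preparation. That the list lay among the highest 2.5% of random lists in 12 of 12 classes is the pattern itself and does not decide between them. An effect of the diet stays open and untested.

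Interferon response and MHC class I genes were lower in beta-like, alpha-like and delta-like cells with gluten. Both medians were also below 0 in every other class for which these lists were fixed. The interferon median was -0.60 in B-like, -0.41 in cDC2-like and -0.31 in mesenchymal-like cells. In T-like, macrophage-like, endothelial-like and cDC1-like cells it lay within the central 95% of random lists. The tests of leukocyte RNA and of scaling cover endocrine cells only. Loss of RNA of T-like and B-like cells floating into alpha-like droplets is argued against. At the make-up of T-like and B-like sums with HC alone, the loss of B2m would need a loss of 10140 CPM of 10 leukocyte genes. That is 752 times the upper bound of the 6.48 CPM that was seen (13.5 CPM). RNA of myeloid cells, and beta-like and delta-like cells, were not part of this test. Scaling is argued against too, as the highest of 18 medians under 3 other scalings was -0.46. Less interferon gamma RNA from fewer T cells stays open. Ifng over all cells was lower as predicted, at -0.46 [-0.58, -0.34]. The smaller share of T-like cells would by itself lower that value, so it does not test a link to the endocrine genes. Ifng within T-like cells stood at -0.04, as fewer cells of the same kind would leave it, whereas Irf1 and Cxcl10, higher in beta-like and alpha-like cells, went the other way. In beta-like cells the interferon medians of the 3 clusters were -0.47, 0.03 and 0.51, so a shift among them is part of the class value, and its cause was not tested. As the clusters were formed from the same expression values, those medians cannot show in which cells the genes had not fallen. An effect of the diet, the pool of mice or the preparation stays untested.

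Acinar enzyme RNA lay in cells of other classes in the library with gluten. Free RNA spread evenly is argued against, since 7.77% of B-like cells held 10 or more acinar UMIs where a Poisson law at the same mean of 2.63 gives 0.0405%. Whole acinar cells caught with another cell are argued against as well, also with doublets and cells rich in acinar RNA left in: 252 carriers with 3 or more UMIs of T or B markers held a median of 23 acinar UMIs, 2.74% of the 840.5 in acinar-like cells. Parcels of acinar RNA of about the same size stay open: the medians of carriers in 12 classes, between 16 and 30 UMIs, differed by a factor of 1.88, between the limits of 1.5 and 3 set for the test, where depth differed by 13.1. The cut at 10 UMIs and the removal of cells rich in acinar RNA limit how far these medians can differ. The lowest, 16 in PP-like and 17 in delta-like cells, were of classes with carriers in both libraries, at 14 and 14.5 UMIs with HC alone. No biological explanation of this pattern was tested.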

How the results depend on the processing

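Scrublet's own threshold, acinar genes kept in clustering, and leaving out cells of 10 or more acinar UMIs or the top cell of each gene, and shares among cells of named subclusters, were alternatives chosen after seeing the data. Of 174 comparisons of a share of all cells with an alternative, 152 stayed within the interval of the main value, 21 left it and 1 reversed. For list medians these counts were 1420, 113 and 14 of 1547, for named genes 2261, 363 and 11 of 2635, and of counts of genes apart 135 of 177 stayed within 1.5 times the main count and 42 did not. For shares of immune cells they were 64 and 6 of 70, for T and NK subclusters 27, 4 and 4 of 35, and for myeloid subclusters 32 and 5 of 37. Some alternatives gave no value: Leiden resolution 0.5 formed no cDC1-like or cDC2-like class, the stricter filter no PP-like class and no gamma delta T or ILC2 subcluster, and subcluster resolution 0.4 no CD4 T, regulatory T, monocyte or cDC1 subcluster. A minimum of 20 or 200 UMIs, or 1.5-fold, changes by construction which genes can count. For the other values below the cause was not tested. Depth limits the smaller classes, as NK-like sums held 811 measured genes and beta-like sums 10912. Shares below are differences in percentage points, gluten minus HC alone, and parentheses name the class.

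Under the stricter cell filter, T and NK subclusters differed by 4.16 (CD4 T) and -1.14 (unnamed). The list median for insulin was 1.88 (endothelial) and -1.42 (macrophage). For ribosomal proteins it was 0.13 (cDC2), 0.019 (macrophage) and -0.032 (mesenchymal). Myeloid subclusters differed by 0.695 (cDC1), 3.91 (macrophage) and -7.53 (monocyte). Glycam1 in endothelial-like cells had a log2 ratio of 0.41. The share of all cells differed by 1.18 (acinar) and -0.027 (acinar-rich).

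With no cell filter, the share of all cells differed by -6.19 (beta) and 7.50 (unnamed). Among immune cells, the share differed by 1.98 (NK).

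With doublets kept, T and NK subclusters differed by 4.77 (CD4 T). The median of insulin was 0.035 (B), 0.12 (T), 0.20 (endothelial) and 0.19 (macrophage). Interferon response stood at -0.43 (endothelial). Islet hormones stood at -0.088 (alpha). Mitochondrial genome stood at 0.24 (cDC2). Proliferation stood at 0.22 (macrophage). Ribosomal proteins stood at 0.23 (PP), -0.10 (T), 0.16 (alpha), 0.0069 (beta), -0.019 (cDC2), -0.021 (endothelial), -0.035 (macrophage) and -0.016 (mesenchymal). Myeloid subclusters differed by 3.04 (macrophage) and 6.86 (unnamed). Glycam1 in endothelial-like cells had a log2 ratio of 0.57. The share of all cells differed by 0.962 (unnamed).

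At Scrublet's own threshold, the count of genes 2-fold apart was 498 (cDC2) and 205 (endothelial). The list median for MHC class I was -0.32 (macrophage). For MHC class II it was -0.31 (cDC2). For insulin it was 0.037 (B), 0.13 (T), 0.75 (endothelial) and 1.29 (macrophage). For interferon response it was -0.44 (endothelial). For islet hormones it was -0.10 (alpha). For mitochondrial genome it was 0.22 (cDC2). For proliferation it was 0.087 (macrophage). For ribosomal proteins it was -0.10 (T), 0.050 (beta), -0.18 (cDC2), -0.14 (endothelial), -0.10 (macrophage) and -0.016 (mesenchymal). Glycam1 in endothelial-like cells had a log2 ratio of 0.51. The share of all cells differed by 0.889 (unnamed).

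At Leiden resolution 0.5, acinar enzymes had a list median of 2.65 (PP). Insulin had 0.76 (T). Proliferation had 0.32 (T). Ribosomal proteins had 0.072 (PP), -0.12 (T) and 0.12 (delta). Limch1 in PP-like cells had a log2 ratio of 0.13 and Ppy in PP-like cells had a log2 ratio of 0.37. The share of all cells differed by -0.017 (PP), -0.635 (acinar), 4.70 (delta), 2.41 (plasma) and 0.541 (unnamed). Among immune cells, the share differed by 6.46 (plasma).

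At Leiden resolution 2, the median of insulin was -0.61 (macrophage). Ribosomal proteins stood at 0.013 (macrophage).

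With classes from a marker score per cell, the share of all cells differed by -0.396 (NK), 2.13 (PP), 3.05 (acinar), -0.070 (acinar-rich) and 0.377 (cDC1). Among immune cells, the share differed by 0.204 (NK), 1.62 (cDC1) and 1.63 (cDC2).

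With acinar genes kept in clustering, acinar enzymes had a list median of 1.37 (B), 1.61 (T) and 1.03 (alpha). Interferon response had -0.62 (beta). Proliferation had 0.022 (T). Ribosomal proteins had 0.23 (PP), -0.10 (T) and 0.018 (cDC1). Ighm in B-like cells had a log2 ratio of -0.70, Igkc in B-like cells had a log2 ratio of -0.37 and Nkg7 in T-like cells had a log2 ratio of -0.017. The share of all cells differed by -3.14 (B), 1.81 (acinar), -0.028 (acinar-rich), 5.35 (alpha), 0.196 (plasma) and 3.76 (unnamed). Among immune cells, the share differed by 0.649 (plasma).

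Without cells of 10 or more acinar UMIs, the median of acinar enzymes was 1.25 (B), 0.057 (PP), 1.13 (T), 0.96 (alpha), 0.43 (beta), 0.61 (cDC1), 1.13 (cDC2), 1.13 (delta), 1.11 (endothelial), 1.21 (macrophage) and 1.05 (mesenchymal). Mitochondrial genome stood at 0.079 (PP). Ribosomal proteins stood at 0.23 (PP). Gluten-related genes stood at 0.58 (beta).

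Without the top cell of each gene, the list median for acinar enzymes was 3.23 (alpha). For insulin it was 0.93 (endothelial) and -0.71 (macrophage). For ribosomal proteins it was 0.34 (PP), -0.041 (endothelial) and 0.012 (macrophage). Gzma in NK-like cells had a log2 ratio of 0.16.

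With TMM scaling, MHC class II had a list median of 0.17 (cDC2). Insulin had 1.01 (B). Mitochondrial genome had 0.51 (cDC2). Ribosomal proteins had 0.12 (B), 0.093 (NK), 0.21 (PP), -0.031 (T), 0.16 (alpha), 0.22 (cDC2), 0.16 (delta), -0.0066 (endothelial), 0.079 (macrophage) and -0.034 (mesenchymal).

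With median-of-ratios scaling, the median of MHC class II was 0.14 (cDC2). Insulin stood at 1.01 (B) and -1.16 (macrophage). Mitochondrial genome stood at 0.092 (PP) and 0.48 (cDC2). Ribosomal proteins stood at 0.11 (B), 0.062 (NK), 0.20 (PP), -0.034 (T), 0.15 (alpha), 0.19 (cDC2), 0.15 (delta), -0.0101 (endothelial), 0.090 (macrophage) and -0.025 (mesenchymal).

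With CPM without hormone, enzyme and mitochondrial genes, the list median for insulin was 0.94 (B). For mitochondrial genome it was 0.051 (PP). For ribosomal proteins it was 0.044 (B), 0.16 (PP), 0.10 (alpha), -0.034 (beta) and -0.053 (endothelial).

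By means of per-cell CPM, the count of genes 2-fold apart was 346 (beta), 190 (cDC1), 193 (endothelial) and 379 (macrophage). MHC class II had a list median of 0.084 (cDC2) and -1.08 (endothelial). Acinar enzymes had 3.18 (beta). Insulin had 0.93 (B), 0.64 (T), 1.26 (endothelial) and 0.43 (macrophage). Islet hormones had -0.11 (alpha). Mitochondrial genome had 0.079 (PP) and -0.13 (cDC1). Proliferation had 0.092 (T). Ribosomal proteins had 0.19 (PP), -0.14 (T), 0.11 (alpha), -0.070 (beta), 0.041 (cDC1), 0.0001 (cDC2), -0.024 (macrophage) and 0.023 (mesenchymal). Cxcl10 in endothelial-like cells had a log2 ratio of -0.14 and Gzma in NK-like cells had a log2 ratio of 0.11.

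At 1.5-fold, the count of genes was 1045 (B), 148 (NK), 672 (PP), 1202 (T), 908 (alpha), 679 (beta), 379 (cDC1), 939 (cDC2), 564 (delta), 494 (endothelial), 781 (macrophage) and 1033 (mesenchymal).

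With a minimum of 20 UMIs, the count of genes 2-fold apart was 626 (B), 250 (NK), 425 (PP), 625 (T), 437 (alpha), 367 (beta), 372 (cDC1), 732 (cDC2), 368 (delta), 328 (endothelial), 620 (macrophage) and 986 (mesenchymal).

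With a minimum of 200 UMIs, the count of genes 2-fold apart was 54 (B), 8 (NK), 41 (PP), 105 (T), 115 (alpha), 108 (beta), 18 (cDC1), 66 (cDC2), 64 (delta), 38 (endothelial), 66 (macrophage) and 107 (mesenchymal).

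At subcluster resolution 0.4, T and NK subclusters differed by 6.67 (unnamed).

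At subcluster resolution 1.5, T and NK subclusters differed by -2.28 (regulatory T).

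Among cells of named subclusters, T and NK subclusters differed by -6.26 (CD4 T), -1.91 (CD8 T) and -0.838 (regulatory T).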

Other observations

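Some genes stood among those farthest apart in several classes at once. The transcription factor Nfil3 was higher with gluten in T-like (2.19), B-like (2.45), cDC2-like (2.29) and cDC1-like cells (3.69). Vps37b, of the sorting machinery of endosomes, was higher in T-like (1.87), NK-like (2.71) and B-like cells (1.43), and Irs2 in beta-like (2.02), T-like (2.16) and B-like cells (1.89). Maff stood between 2.57 and 3.27 in the 4 endocrine classes. The inflammatory microRNA host gene Mir155hg was higher in macrophage-like (4.12) and cDC2-like cells (3.29).

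Within the interferon response, genes that interferon gamma is known to induce went apart. Irf1 was higher in beta-like (1.59), alpha-like (1.26), T-like (0.95) and B-like cells (0.67), and Cxcl10 in those classes and in cDC1-like cells (3.17). Iigp1 was lower in beta-like (-1.61), alpha-like (-1.79), delta-like (-1.93) and cDC1-like cells (-1.50). Ciita was lower in B-like (-0.76), cDC1-like (-0.98) and cDC2-like cells (-0.98), whose MHC class II medians lay between -0.01 and 0.07, or at -0.31 in cDC2-like cells at Scrublet's own threshold.

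Chemokines summed over all cells of a library differed gene by gene. Ltb had -0.37, Lta -0.30, Cxcl9 -0.28 and Ccl22 -0.63, while Ccl19 had 0.25, Cxcl12 0.26, Cxcl10 0.54 and Ccl17 2.44. Ccl21a had -4.10, and 1 cell with HC alone held 568 UMIs of it.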
